A study of Gallus gallus with 20 samples.

How the data were processed

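RNA sequencing was done on total RNA of hypothalamus and pituitary from male Korat chickens of 10 weeks, extracted with TRIzol per the labels' protocols, with an RNA integrity number of at least 7.7 and 1 µg of RNA per library. Each library is a pool of birds, 5 libraries in each of 4 groups by title (low and high residual feed intake, RFI, in each tissue), so p values measure the spread between these pooled samples. The authors deposited a table of raw read counts per gene, and reads were aligned with HISAT2 2.0.5 to the GRCg6a chicken genome, per the submitters' processing notes, which also name DESeq2 1.20.0. The authors also deposited FPKM values, and these equal the count divided by the listed gene length and by a median-ratio-scaled library size, with a largest relative deviation of 2.2e-07. The tool that counted reads and whether strand was used are not given in the sources used here, so antisense and overlapping genes are uncertain. The table holds 28021 genes, and every column of sample values was mapped to 1 library. Symbols, identifiers and coordinates are those of the deposited table; a reference table of another build was not used.

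Libraries of a group were compared with each other, and their counts differed by a chi-square per degree of freedom of 9.18 to 238, so none was the same library sequenced again. This does not show that each library holds its own pool of birds. That stays open in the pituitary, where 4 pools are stated for 5 libraries per group. Depth was 11418600 to 12647034 counts in the hypothalamus and 10262777 to 11960994 in the pituitary. The median standard error of a log2 fold was 0.16 and 0.23, and 0.32 for the difference between tissues.

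Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr, and the robust quasi-likelihood test, each tissue alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 folds are low minus high RFI. The tissue difference was the pituitary fold minus the hypothalamus fold in a fit of all 20 libraries. Levels are CPM, counts relative to the TMM-scaled library size, given as mean ± SD. TMM factors were computed after the low-count filter for the test values and group means and without it for levels of single libraries set against others, so the same gene can differ slightly between them. Levels that tell the tissues apart were scaled over all 20 libraries together, and differ more from those scaled in 1 tissue. Gene lists, 28 of pathways and 15 of cell or tissue markers, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 between genes, for lists with at least 5 measured members. The same lists were tested with an estimated correlation and with fry, whose p asks whether a list's genes move on balance one way and does not compare the list with other genes. Of 43 lists 42 were tested in each tissue; 1 list had too few members. The correlation between tissues was tested by assigning the RFI labels to the pituitary libraries in all 252 ways.

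Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for the changes named below. By that rule the text names genes that passed, up to 12 per direction and tissue, or, where fewer than 5 passed, the 5 protein-coding genes with a symbol of smallest p in each direction. It also names up to 4 members of smallest p from each list, any feeding or releasing neuropeptide in the hypothalamus, and any hormone, lineage factor or receptor in the pituitary. Some results that the rule or a test would give are not reported here. Other genes named are said to be chosen after their values were seen. Several members were not matched by name, among them LHB, GNRH1, IGF1 and GNRHR, and are not analysed here.

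The steps were tested on simulated counts with the means and library sizes of the real samples. Each gene was drawn independently of the others. In the real lists the estimated correlation between genes had a median of 0.152 in the hypothalamus and 0.288 in the pituitary (largest 0.874 and 0.902). The simulation therefore cannot show how often lists of correlated genes are called falsely. With genes raised or lowered by 1.5, 2 and 4 times, the test recovered 32.8, 59.7 and 95.5% in the hypothalamus (15020 genes), 2.99, 35.8 and 72.7% in the pituitary (15585 genes) and 1.49, 29.9 and 59.1% for the tissue difference (16544 genes). Of 130, 75 and 63 calls, 5, 1 and 3 were false. Differences that many genes of a library share were not simulated. These recovered shares and false calls therefore need not hold for the real samples. A list raised in simulation was called by camera with the preset correlation in both tissues (limma, adjusted p = 6.03e-18 and 0.000761), and with an estimated correlation in the hypothalamus (adjusted p = 0.000324) but not in the pituitary (adjusted p = 0.147); fry called it in the hypothalamus (adjusted p = 1.64e-06) but not in the pituitary (adjusted p = 0.220), and with the preset correlation 1 other list was called in the pituitary.

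Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile scaling, no low-count filter, a filter of 50 counts in 5 libraries, limma on log2 FPKM with pseudocounts of 1 and 0.1 (FPKM of at least 0.5, or no filter), 1 spread shared over all libraries, a block for the replicate number, and leaving out each library in turn. Chosen after the data were seen were the fits without pituitary low RFI library 1 and high RFI library 4, the fits without low RFI libraries 2 and 4 as well, and a fit with a score of small chromosomes as a covariate.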

Results

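Korat chickens are a slow-growing chicken line, and the birds measured were males kept in individual cages to 10 weeks of age. Residual feed intake (RFI) is the difference between the feed a bird eats and the feed predicted from its weight and growth, so a bird with a low value eats less than predicted. From 200 males, birds at the low and the high end of RFI were chosen, and RNA of their hypothalamus and pituitary was pooled and sequenced. The titles give 5 libraries for each of 4 groups, low and high RFI in each tissue, 20 in all. For the hypothalamus the design text describes 10 birds per group in 5 pools, which matches the titles. For the pituitary it describes 8 birds per group, 2 to a pool, and 4 pools per group, where the titles list 5 libraries per group; the 5 were used as labelled. Each library is a pool of RNA, so the spread between libraries is the spread between pools and is smaller than that between single birds would be. Hypothalamus libraries held 11418600 to 12647034 counts and 19981 to 20376 genes with a count. Pituitary libraries held 10262777 to 11960994 counts and 20522 to 21038 genes. The mitochondrial share was 13.9 to 20.1% of counts in the hypothalamus and 5.18 to 10.96% in the pituitary. The median standard error of a log2 fold was 0.16 in the hypothalamus and 0.23 in the pituitary.

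The tissues were told apart by their own transcripts, with levels on 1 scale shared by all 20 libraries, which puts pituitary means below those given later on the scale of that tissue alone. Growth hormone (GH) averaged 31080 ± 13990 CPM (counts scaled to library size; SD, n = 10) in the pituitary and 3.20 ± 2.65 in the hypothalamus. The prohormone POMC averaged 18290 ± 6849 CPM in the pituitary and 7.36 ± 6.40 in the hypothalamus, while the myelin gene MBP averaged 2881 ± 3763 and 23450 ± 5313. Several single libraries stood apart from the other 9 of their tissue. Hypothalamus low RFI library 2 held 23400 CPM of transthyretin (TTR) against at most 72.7 elsewhere, and 1060 CPM of ASMT, the last enzyme of melatonin synthesis, against at most 2.15. In the pituitary, low RFI library 1 held 42.3 CPM of the diencephalic factor GBX2 and 228 of the GABA-synthesis gene GAD1, against at most 0.348 and 62.3 in the others. Pituitary high RFI library 4 held 75.5 CPM of EN2 and 139 of FAT2 against at most 1.97 and 2.85. The sodium channel gene SCN11A of sensory neurons stood at 542 CPM in pituitary low RFI library 2 and at most 27.2 elsewhere. Pituitary low RFI library 4 held 340 CPM of the chitinase CHIA and 223 of the epithelial antibody receptor PIGR, against at most 1.26 and 1.17. These genes were chosen after their values were seen. On the first principal component of the pituitary, which took 40.8% of the variance, low RFI library 1 lay at -108 and high RFI library 4 at -62.7, and all others between 0.109 and 42.6.

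**Figure D1:**
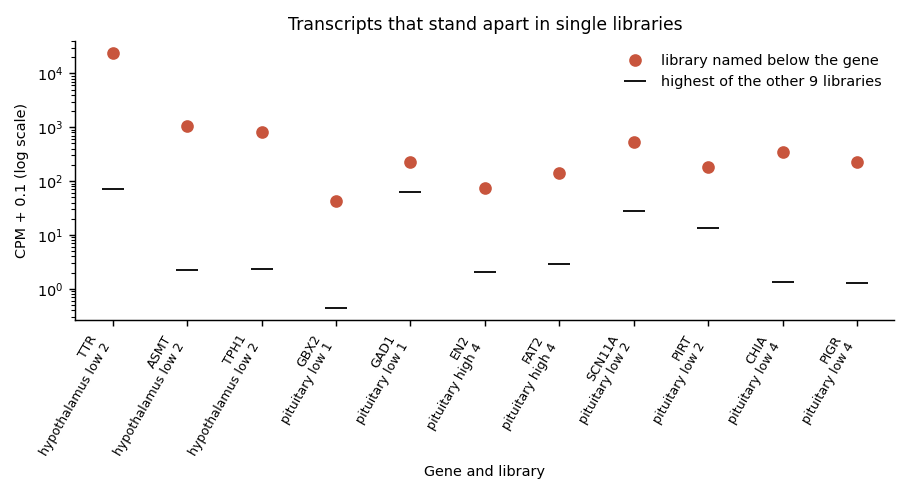
Level of marker genes of other tissues (CPM + 0.1, log scale) in the library where each is highest and in the highest of the other 9 libraries of that tissue. TTR stands at 23400 against 72.7 CPM in hypothalamus low RFI library 2 and EN2 at 75.5 against 1.97 CPM in pituitary high RFI library 4.

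The first comparison asked which transcripts of the hypothalamus, the brain region that controls appetite and the release of pituitary hormones, differ between birds of low and high RFI. The smallest p values among genes higher in low RFI belonged to the choline acetyltransferase gene CHAT, the granin gene CHGB of secretory granules, the choline transporter gene SLC5A7, and the cadherin genes CDH9 and CDH11. CHAT (ENSGALG00000002289, chromosome 6, 3650070 to 3681305) averaged 6.40 ± 3.38 CPM in low RFI and 2.15 ± 0.453 in high RFI pools (SD, n = 5 each), a log2 fold of 1.57 with a standard error of 0.32, and all 5 low RFI libraries lay above all high RFI ones. SLC5A7 (ENSGALG00000016804, chromosome 1, 137344058 to 137365066) averaged 12.5 ± 7.61 against 4.19 ± 1.36 CPM (log2 fold 1.58, SE 0.38). CHGB (ENSGALG00000046616, chromosome 3, 16985845 to 16997906) averaged 643.9 ± 47.7 against 439.5 ± 90.8 CPM (log2 fold 0.55, SE 0.12). The log2 folds of CDH9 and CDH11 were 0.61 (SE 0.16) and 0.30 (SE 0.08). None of these passed the test across all genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.964 each).

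Among genes lower in low RFI hypothalamus with the smallest p values was the peroxidase gene EPX, at 0.810 ± 0.202 CPM in low RFI and 2.45 ± 1.101 in high RFI pools (SD, n = 5 each), a log2 fold of -1.58 (SE 0.35). PYGO2, a coactivator of Wnt signalling, averaged 10.5 ± 0.581 against 13.9 ± 0.941 CPM (log2 fold -0.41). All 5 low RFI libraries lay below all high RFI ones for both genes. CD1B and CCDC130 had log2 folds of -0.64 and -0.54, and each of the 4 had adjusted p = 0.964 (edgeR, Benjamini-Hochberg). CD1B belongs to a family of similar genes whose reads can be shared, so its value is uncertain. By chromosome, the median log2 fold was -0.32 (SE of the median 0.04) over the 122 tested genes on unplaced scaffolds and -0.14 (SE 0.01) over the 834 on chromosomes 16, 25 and 30 to 33. It was 0.03 over the 7193 on chromosomes 1 to 5 and Z. In the pituitary the same classes had medians of 0.01 (140 genes on scaffolds, SE 0.05) and 0.01 (855 genes).

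**Figure D2:**
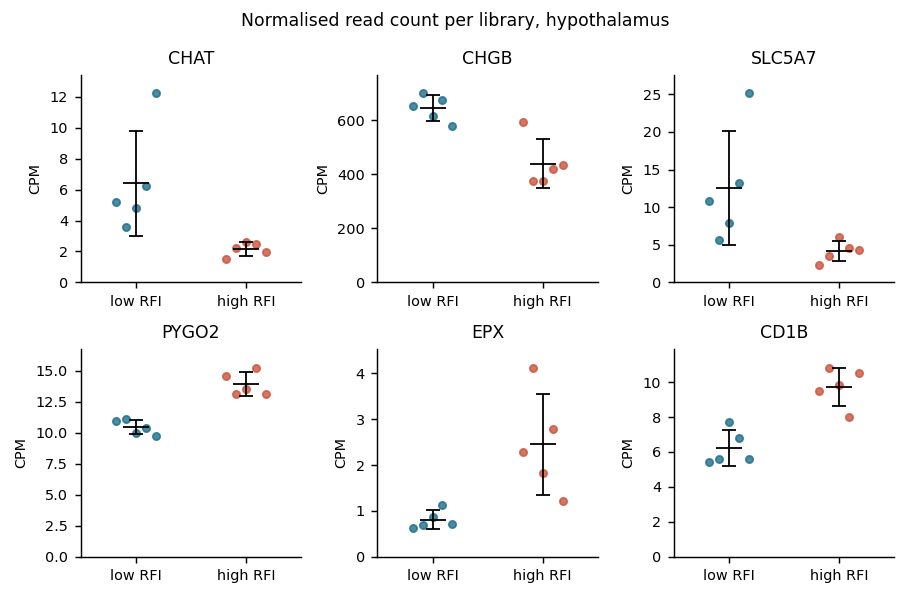
Normalised read count (CPM) of 6 genes in each of the 10 hypothalamus libraries, with the mean and SD of each RFI group (n = 5). All 5 low RFI libraries lie above all high RFI ones for CHAT and below them for PYGO2, and no gene passed the test across all genes.

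**Figure D3:**
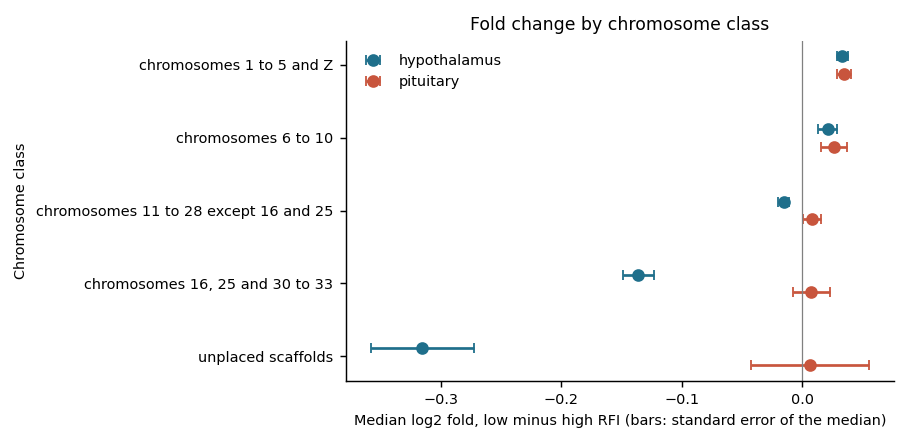
Median log2 fold (low minus high RFI) of the tested genes in each class of chromosome, with the standard error of the median as bars, in each tissue. In the hypothalamus the median is -0.32 on unplaced scaffolds and 0.03 on chromosomes 1 to 5 and Z, and in the pituitary it is 0.01 and 0.03.

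Across the hypothalamus, 0 of 15179 genes passed at an adjusted p under 0.05 with edgeR. At an unadjusted p under 0.05 there were 728 genes, 306 higher and 422 lower in low RFI, where 759 would be reached by chance. In 140 genes (0.922%) the groups did not overlap, and chance gives 0.794%. DESeq2 called 5 genes (965 at unadjusted p under 0.05) and limma-voom 0 (987). Among them were CHAT (DESeq2 adjusted p = 0.0317), the unnamed gene ENSGALG00000052652 (log2 fold -0.52) and 2 gene models without a symbol (log2 folds -1.34 and -0.89); the last 3 were named after their values were seen.

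Of 39 feeding-related neuropeptide genes listed beforehand, 24 were tested in the hypothalamus, and none passed. GHRH, which releases growth hormone, averaged 14.4 ± 4.95 CPM in low RFI and 7.36 in high RFI pools, and tyrosine hydroxylase (TH), the dopamine-synthesis enzyme, 14.7 ± 12.7 against 5.72. The appetite-raising NPY averaged 76.8 ± 42.5 against 84.2 CPM, POMC 7.80 ± 6.17 against 5.47, and CARTPT 9.19 ± 4.26 against 5.31. CRH, the stress-axis releasing hormone, averaged 25.1 ± 11.1 against 17.2 CPM and NPVF, the gonadotropin-inhibitory hormone, 33.3 ± 28.9 against 17.0. Single libraries carried some of these means: TH was 35.58 CPM in low RFI library 4, without which the low RFI mean was 9.53, and 2.53 in low RFI library 2, under every high RFI library. NPVF was 21.2 in low RFI without library 5 and 8.31 in high RFI without library 5, and POMC was 3.11 in high RFI without library 3. The antidiuretic peptide gene AVP ranged from 25.04 to 440.3 CPM in low RFI libraries and from 77.9 to 1123 in high RFI ones. As groups, 18 of 24 feeding neuropeptides were higher in low RFI (camera, Benjamini-Hochberg adjusted p = 0.0898), and so were 7 of 10 releasing hormones and posterior pituitary peptides (adjusted p = 0.187). Adjusted over the list alone, 0 members of either list passed. The member taken as mesotocin by its alias is metallothionein 3 and says nothing of mesotocin. That member belongs to both lists and to the list of hypothalamic neuron genes, and the releasing hormone list also holds the enzyme gene TH.

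Of 42 gene lists tested in the hypothalamus, 7 were called by camera with a preset correlation of 0.01 between genes, 6 higher and 1 lower in low RFI. None of the 7 held with an estimated correlation, where the smallest adjusted p over all lists was 0.297, and fry called 0 lists (smallest adjusted p = 0.415). Genes of prohormone processing and dense-core granules were higher, 19 of 22 (median log2 difference 0.16, camera with Benjamini-Hochberg adjusted p = 0.000604; adjusted p = 0.639 with an estimated correlation). Its members CHGB, SYT4, SCG2 and PCSK2, which package, sort or process peptide hormones, had log2 folds of 0.55, 0.38, 0.30 and 0.31. CHGB passed when adjusted over the list alone (1 of 22, adjusted p = 0.0166 in edgeR). All 7 measured genes of the anterior pituitary hormone list were higher by mean log2 CPM (median 0.57, camera adjusted p = 0.00505; adjusted p = 0.297 with an estimated correlation). That list holds CHGB, which passed adjusted over the list alone (1 of 7, adjusted p = 0.00528), and its members GH and GAL had edgeR log2 folds of -0.21 and -0.11, opposite to the list. Both calls were kept when any 1 of the 10 libraries was left out. The hormone list median was 0.29 without high RFI library 1 and 0.88 without 5. Markers of anterior pituitary endocrine cells were higher in 6 of 6 members by mean log2 CPM (median 0.42) and were not called (camera adjusted p = 0.169). That list shares members with the hormone list, among them CGA, POMC and GH, the last with the edgeR log2 fold of -0.21.

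Interferon-stimulated genes were higher in low RFI hypothalamus, 24 of 26 (median log2 difference 0.33, camera with Benjamini-Hochberg adjusted p = 3.99e-05; adjusted p = 0.639 with an estimated correlation). IFIT5 stood at 94.3 and 123.9 CPM in low RFI libraries 1 and 2, and at 9.59 to 38.9 in the other 8, and the log2 fold of the RNA sensor gene IFIH1 was 0.38. Without low RFI library 2, which also held the TTR and ASMT reads, the call was lost (adjusted p = 0.0667). IFIT5, at a log2 fold of 1.41, fell to 0.94 and IFIH1 to 0.24 there. The interferon list median was 0.15 without low RFI library 2. Myelinating oligodendrocyte markers were lower, 12 of 14 (median -0.35, camera adjusted p = 0.00133; adjusted p = 0.639 with an estimated correlation). Their examples were SOX10 at a log2 fold of -0.33, the myelin enzyme gene CNP at -0.39 and HAPLN2 at -0.38. Low RFI library 2 had the lowest list mean, -0.61 on the log2 scale around the mean of all libraries, and the call was kept whichever library was left out. Without that library the oligodendrocyte median fell to -0.18 (adjusted p = 0.0242), CNP to -0.25 and HAPLN2 to -0.22. Fibroblast and meninges markers were higher, 14 of 14 (median 0.35, camera adjusted p = 0.0114; adjusted p = 0.639 with an estimated correlation), with IGFBP2 at a log2 fold of 0.24 and COL1A2 at 0.55. That call was lost without low RFI library 1 (adjusted p = 0.0636), 2 (0.0791) or 3 (0.0815) or high RFI library 1 (0.136) or 3 (0.122). The fibroblast and meninges median was 0.20 without low RFI library 2, 0.52 without 4, 0.20 without high RFI library 1, 0.19 without 3 and 0.55 without 5. IGFBP2 fell to 0.15 and COL1A2 to 0.32 without low RFI library 2. No member (0) of these 3 lists passed when adjusted over the list alone.

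Monoamine genes were higher in low RFI hypothalamus, 20 of 30 (median log2 difference 0.24, camera with Benjamini-Hochberg adjusted p = 0.0285; adjusted p = 0.639 with an estimated correlation). Aromatic amino acid decarboxylase (DDC) had a log2 fold of 1.83, GCH1, which makes the cofactor of monoamine synthesis, 2.36, the serotonin-synthesis gene TPH2 2.52 and the serotonin transporter gene SLC6A4 2.85. These levels were uneven within the group. TPH2 stood at 146.0 and 118.5 CPM in low RFI libraries 3 and 4 and at 6.16 to 27.9 in the other 8. GCH1 stood at 44.8 CPM in low RFI library 2, which also held the TTR and ASMT reads. The fold of GCH1 fell to 1.34 without that library and that of SLC6A4 to 1.89 without low RFI library 4. The call was lost without low RFI library 2 (adjusted p = 0.0596), 3 (0.0897), 4 (0.134) or 5 (0.0652) or high RFI library 3 (0.124) or 5 (0.0660). The monoamine list median was 0.11 without low RFI library 5, 0.14 without high RFI library 1 and 0.14 without 3. Receptors for feeding-related signals were higher, 22 of 32 (median 0.13, camera adjusted p = 0.0333; adjusted p = 0.639 with an estimated correlation). Their examples were GFRAL, the GDF15 receptor, at a log2 fold of 0.75, MRAP2, a melanocortin receptor partner, at 0.59, HTR1B at 0.31 and NPY5R at 0.33. That call was lost without low RFI library 3 (adjusted p = 0.0532), 4 (0.193) or 5 (0.210) or high RFI library 3 (0.114). The feeding receptor median was 0.21 without low RFI library 2, 0.06 without 4, 0.014 without 5, 0.078 without high RFI library 4 and 0.22 without 5. Adjusted over the list alone, 0 members of either list passed. HTR1B belongs to both lists. The other 35 lists had camera adjusted p values from 0.0514 to 0.916. Over all lists, the number called ran from 4 without high RFI library 3 to 15 without high RFI library 5. The median, mean and test differed in sign for neighbouring forebrain, erythrocyte, folliculostellate, endothelium and inflammation lists, none of them called.

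The pituitary comparison asked the same of the gland that releases growth hormone, prolactin, corticotropin, thyrotropin and gonadotropins. None of the hormone transcripts given here differed between low and high RFI by more than the spread between pools. GH averaged 32520 ± 18950 CPM in low RFI and 36220 ± 12460 in high RFI pools (SD, n = 5 each), prolactin (PRL) 6493 ± 3853 against 6785 ± 2901, and POMC 20610 ± 8121 against 19850 ± 7541. The shared glycoprotein hormone subunit CGA averaged 9573 ± 5044 against 9719 ± 3909 CPM, TSHB 593.3 ± 339.7 against 620.6 ± 343.8, and FSHB 670.5 ± 380.7 against 707.4 ± 592.8. Of 10 hormone and granin genes, 9 were lower in low RFI by mean log2 CPM, and the list did not pass (camera with Benjamini-Hochberg adjusted p = 0.168). FSHB stood at 86.8 CPM in low RFI library 2, which also held the SCN11A reads, and at 585 or more in the other 4 of that group.

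**Figure D4:**
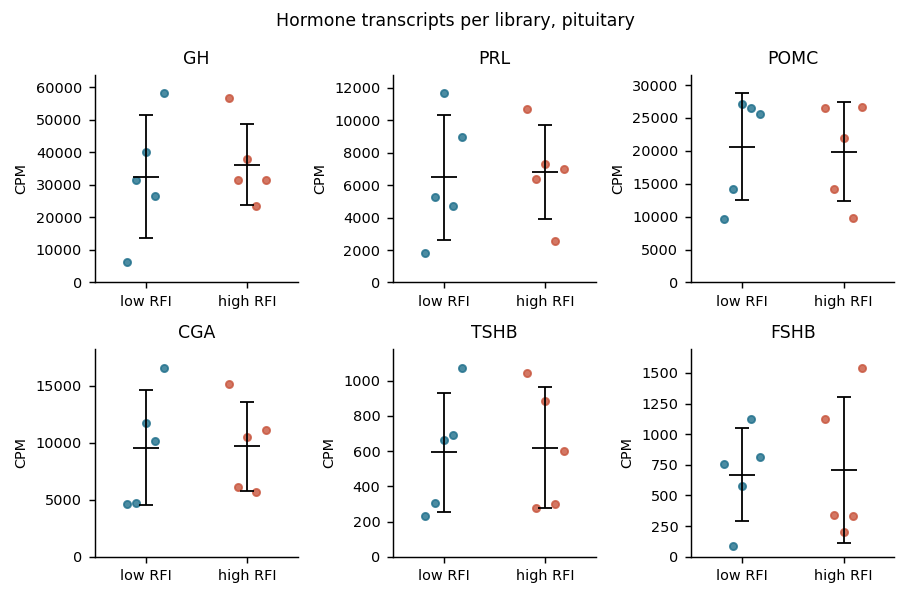
Normalised read count (CPM) of 6 pituitary hormone genes in each of the 10 pituitary libraries, with the mean and SD of each RFI group (n = 5). The groups overlap for all 6 genes, with GH at 32520 ± 18950 against 36220 ± 12460 CPM.

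Among single pituitary genes, those with the smallest p values on the higher side included the lipid kinase gene DGKH, the potassium channel gene KCNJ8, COMTD1 and WDR31. KCNJ8 (ENSGALG00000026373, chromosome 1, 66955605 to 66963463) averaged 30.1 ± 2.23 CPM in low RFI and 23.7 ± 1.89 in high RFI pools (SD, n = 5 each), a log2 fold of 0.34 (SE 0.10), with all 5 low RFI libraries above all high RFI ones. DGKH had a log2 fold of 1.70 (SE 0.46), WDR31 1.34 and COMTD1 0.93. On the lower side stood PDE6B, a phosphodiesterase subunit gene, the dicarboxylate transporter gene SLC13A3, ITIH2, the growth factor gene GDF11 and SLC6A13, a GABA transporter gene of the meninges. PDE6B (ENSGALG00000015373, chromosome Z, 53575086 to 53596769) averaged 3.67 ± 1.13 against 8.52 ± 2.08 CPM, a log2 fold of -1.21 (SE 0.27), with all 5 low RFI libraries below. SLC6A13 (ENSGALG00000012985, chromosome 1, 60190170 to 60217228) averaged 7.11 ± 2.42 against 20.8 ± 10.5 CPM (log2 fold -1.54, SE 0.38). The log2 folds of SLC13A3, ITIH2 and GDF11 were -1.42, -1.85 and -0.87. Each of these 9 had adjusted p = 0.999 (edgeR quasi-likelihood, Benjamini-Hochberg).

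**Figure D5:**
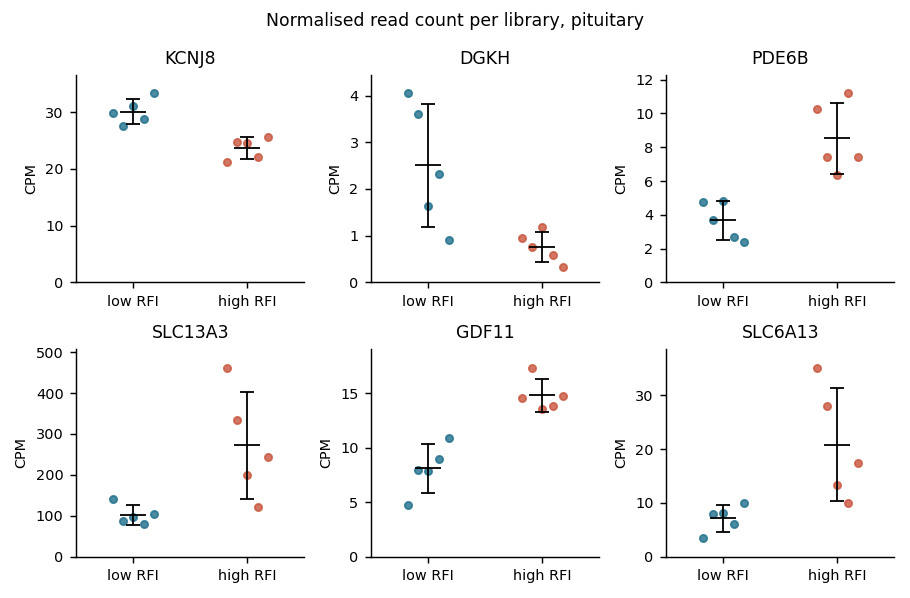
Normalised read count (CPM) of 6 genes in each of the 10 pituitary libraries, with the mean and SD of each RFI group (n = 5). All 5 low RFI libraries lie above all high RFI ones for KCNJ8 and below them for PDE6B, and no gene passed the test across all genes.

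Across the pituitary, 0 of 15786 genes passed at an adjusted p under 0.05 with edgeR. At an unadjusted p under 0.05 there were 296 genes, 130 higher and 166 lower in low RFI, where 789.3 would be reached by chance. In 42 genes (0.266%) the groups did not overlap, and chance gives 0.794%. DESeq2 called 0 genes (512 at unadjusted p under 0.05) and limma-voom 0 (525). With low RFI library 1 and high RFI library 4 left out, edgeR called 0 (447 at unadjusted p under 0.05), and with low RFI libraries 2 and 4 left out as well, 0 (711). On log2(FPKM + 0.1), limma called 1, RF00493_ENSGALG00000025003 (log2 fold -3.87, Benjamini-Hochberg adjusted p = 0.0273), which is named here after its value was seen.

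Of 42 gene lists tested in the pituitary, 18 were called by camera with the preset correlation, 5 higher and 13 lower in low RFI. Several of these lists share members, so the calls are not separate findings. COL1A2 is in the fibroblast and matrix lists, CSF1R in the inflammation and microglia lists, and VIM in the astrocyte and folliculostellate lists. With an estimated correlation 0 were called (smallest adjusted p = 0.184), and fry called 0 (smallest adjusted p = 0.422). With low RFI library 1 and high RFI library 4 left out 17 were called, and 17 with low RFI libraries 2 and 4 left out as well. Fibroblast and meninges markers were lower, 16 of 16 (median log2 difference -0.43, camera with Benjamini-Hochberg adjusted p = 5.43e-07; adjusted p = 0.454 with an estimated correlation), and the call was kept whichever library was left out. Adjusted over the list alone 2 of 16 passed, SLC6A13 and CRABP2, a retinoic acid-binding protein gene (edgeR adjusted p = 0.0356 each; log2 folds -1.54 and -1.22), and 0 over all genes tested. The meningeal genes TBX18 and ALDH1A2 had log2 folds of -0.63 and -0.43. The list mean, centred on the 10 libraries, was -1.42 in low RFI library 1, where GBX2 was highest, and 1.29 in high RFI library 2. Skeletal muscle markers, not called (camera adjusted p = 0.3355), had means of -4.15 and 2.49 in these libraries. In high RFI library 4 the muscle mean was -3.1 and that of the fibroblast and meninges list -0.0968. The fibroblast and meninges median was -0.73 without low RFI library 2 and -0.29 without high RFI library 2. TBX18 fell to -0.35 without high RFI library 2. Extracellular matrix genes were lower, 34 of 38 (median -0.29, camera adjusted p = 5.43e-07; adjusted p = 0.644 with an estimated correlation), with ADAMTS2 at a log2 fold of -0.35, the collagen gene COL12A1 at -0.78, fibronectin (FN1) at -0.49 and LAMC1 at -0.27. Without low RFI library 1 that call was lost (adjusted p = 0.158). The matrix list median was -0.10 without low RFI library 1, -0.47 without 2, -0.15 without high RFI library 2 and -0.19 with low RFI library 1 and high RFI library 4 left out. Without high RFI library 2 ADAMTS2 was -0.23, COL12A1 -0.44, FN1 -0.24 and LAMC1 -0.15. In the matrix list 0 of 38 members passed, over all genes tested or adjusted over the list alone.

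Inflammatory genes were lower in low RFI pituitary, 20 of 25 (median log2 difference -0.26, camera with Benjamini-Hochberg adjusted p = 0.000439; adjusted p = 0.454 with an estimated correlation). The prostaglandin-synthesis gene PTGS2 had a log2 fold of -1.03, with 128 CPM in high RFI library 4 and 32.1 to 37.5 in the other high RFI libraries, the receptor gene TLR2-1 -0.38 and TNFAIP2 -0.76, while the NF-kappaB inhibitor gene NFKBIA stood at 0.56, opposite to the list. Without low RFI library 1 the call was lost (adjusted p = 0.164). The inflammation list median was -0.06 without low RFI library 1. PTGS2 was -0.41 without high RFI library 4 and TNFAIP2 -0.51 without high RFI library 2. Microglia and macrophage markers were lower, 13 of 13 (median -0.23, camera adjusted p = 0.00714; adjusted p = 0.644 with an estimated correlation), with CSF1R at a log2 fold of -0.22 and the complement gene C1QA at -0.27. That call was lost without low RFI library 1 (adjusted p = 0.249) or 4 (0.105) or high RFI library 2 (0.165), without low RFI library 1 and high RFI library 4 together (0.0530), and with low RFI libraries 2 and 4 left out as well (0.419). The microglia list median was -0.13 without low RFI library 1, -0.36 without 2, -0.13 without 4, -0.11 without high RFI library 2 and -0.083 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. CSF1R was -0.33, -0.14 and -0.11 without low RFI library 2, 3 and 4 and -0.10 without high RFI library 2, and C1QA -0.12 without low RFI library 1 and -0.0084 without high RFI library 2. No member (0) of either list passed when adjusted over the list alone.

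Lists of brain-type genes also differed in the pituitary. Hypothalamic neuron genes were lower in low RFI, 16 of 18 (median log2 difference -0.32, camera with Benjamini-Hochberg adjusted p = 1.92e-06; adjusted p = 0.184 with an estimated correlation), and the call was kept whichever library was left out. The neuropeptide gene VIP had a log2 fold of -1.67, the histamine-synthesis gene HDC -1.46 and the forebrain factor gene NKX2-1 -1.52, while AVP stood at 2.88, opposite to the list, with 100 CPM in low RFI library 1 and at most 8.27 elsewhere; without that library its fold was -1.54. NKX2-1 stood at 27.6 CPM in high RFI library 4 and at most 9.98 in the other high RFI libraries, and the list mean was highest there (1.1 around the mean of all libraries); without it the fold of NKX2-1 was -0.98. The hypothalamic neuron median was -0.56 without low RFI library 1 and -0.49 without 2. Feeding neuropeptides were lower, 14 of 22 (median -0.13, camera adjusted p = 0.00396; adjusted p = 0.454 with an estimated correlation), and the call was lost without high RFI library 4 (0.0598). The feeding neuropeptide median was -0.37 without low RFI library 1, -0.33 without 2, -0.20 without 5, -0.37 without high RFI library 1, -0.21 without 3, -0.42 without 5, -0.085 with low RFI library 1 and high RFI library 4 left out and -0.49 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Releasing hormones and posterior pituitary peptides were lower, 4 of 6 (median -0.81, camera adjusted p = 0.0447; adjusted p = 0.518 with an estimated correlation). That call was lost without low RFI library 3 (adjusted p = 0.0874) or 4 (0.0775) or high RFI library 2 (0.0923) or 4 (0.233). The releasing hormone median was -1.64 without low RFI library 1, -1.33 without 3, -1.53 without high RFI library 3, -0.52 without 4, -1.66 without 5, -1.35 with low RFI library 1 and high RFI library 4 left out and -1.41 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Adjusted over the list alone, 0 members of these 3 lists passed. The 3 lists share members, among them VIP and AVP, so their calls are not independent. All 3 were also written with the mesotocin alias that matches metallothionein 3.

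Astrocyte and tanycyte genes were lower in low RFI pituitary, 12 of 14 (median log2 difference -0.31, camera with Benjamini-Hochberg adjusted p = 0.00714; adjusted p = 0.604 with an estimated correlation). Vimentin (VIM) had a log2 fold of -0.63 and CRYM, a thyroid hormone-binding protein gene, -0.59. With low RFI library 1 and high RFI library 4 left out VIM was -0.41 and CRYM -0.26, and CRYM was -0.13 with low RFI libraries 2 and 4 left out as well and -0.20 with limma-voom. The call was lost without low RFI library 3 (adjusted p = 0.162) or high RFI library 4 (0.206). The astrocyte list median was -0.61 without low RFI library 1, -0.17 without 2, -0.14 without 3, -0.20 without 5, -0.20 without high RFI library 2, -0.10 without 4, -0.49 without 5 and -0.61 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Folliculostellate and pituicyte genes were lower, 12 of 14 (median -0.20, camera adjusted p = 0.00801; adjusted p = 0.454 with an estimated correlation), and the call was lost without low RFI library 1 (adjusted p = 0.0939) or 2 (0.108) and with low RFI libraries 1, 2 and 4 and high RFI library 4 left out (0.249). The folliculostellate list median was -0.13 without low RFI library 2, -0.34 without 4 and -0.13 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Thyroid hormone axis genes were lower, 12 of 14 (median -0.09, camera adjusted p = 0.00289; adjusted p = 0.454 with an estimated correlation), with the thyrotropin receptor gene TSHR at a log2 fold of -1.46 and the thyroid hormone transporter gene SLCO1C1 at -1.71. No single library ended that call, but leaving out those 4 did (adjusted p = 0.406). The thyroid axis median was -0.056 without low RFI library 2, -0.20 without 3, -0.14 without 4, -0.19 without 5, -0.018 without high RFI library 1, -0.19 without 2, -0.029 without 3 and -0.25 without 4. Synaptic genes were higher, 23 of 26 (median 0.21, camera adjusted p = 0.0240; adjusted p = 0.803 with an estimated correlation), with SYT2 at a log2 fold of 2.39; their list mean was 1.81 in low RFI library 1 and 1.19 in high RFI library 4, and at most 0.204 elsewhere. Without low RFI library 1 the median turned to -0.14 (adjusted p = 0.164), and the call was also lost without high RFI library 1 (0.327), 2 (0.353) or 5 (0.133) and without those 4 libraries (0.457). The synaptic list median was -0.14 without low RFI library 1, 0.36 without 3, 0.31 without 4, 0.44 without 5, 0.077 without high RFI library 1, 0.083 without 2, 0.55 without 4, 0.082 without 5 and -0.12 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. SYT2 was 0.76 without low RFI library 1. Choroid plexus and ependyma genes were higher, 13 of 17 (median 0.25, camera adjusted p = 0.0198; adjusted p = 0.644 with an estimated correlation), with FOLR1 at 93.7 CPM in low RFI library 4 and at most 1.84 elsewhere. Without low RFI library 4 the median turned to -0.07 (adjusted p = 0.892), and the call was also lost without low RFI library 1 (0.0784) or high RFI library 4 (0.0715) or 5 (0.0643), without low RFI library 1 and high RFI library 4 together (0.118), and without the 4 (0.657). The choroid plexus median was -0.065 without low RFI library 4 and 0.12 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. No member (0) of these 5 lists passed when adjusted over the list alone.

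Growth hormone and IGF axis genes were lower in low RFI pituitary, 20 of 25 (median log2 difference -0.20, camera with Benjamini-Hochberg adjusted p = 0.00919; adjusted p = 0.454 with an estimated correlation). The growth factor gene IGF2 had a log2 fold of -0.71 and the binding protein gene IGFBP5 -0.61. The call was lost without low RFI library 1 (adjusted p = 0.429), without low RFI library 1 and high RFI library 4 together (0.148), and with low RFI libraries 2 and 4 left out as well (0.598). The growth hormone list median was -0.018 without low RFI library 1, -0.03 with low RFI library 1 and high RFI library 4 left out and -0.087 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Pituitary lineage factors and releasing hormone receptors were lower, 23 of 28 (median -0.15, camera adjusted p = 0.0240; adjusted p = 0.803 with an estimated correlation). The glucocorticoid receptor gene NR3C1 averaged 12.8 ± 3.18 CPM in low RFI and 16.6 ± 0.957 in high RFI pools, the lineage factor gene PITX1 168.8 ± 60.1 against 205.3 ± 46.6, POU1F1 524.1 ± 210.3 against 542.2 ± 109.6, and the receptor gene GHRHR 203.6 ± 133.6 against 196.2 ± 37.9. That call was lost without low RFI library 1 (adjusted p = 0.974, median 0.03) or 2 (0.200) or high RFI library 3 (0.106) or 5 (0.269), without low RFI library 1 and high RFI library 4 together (0.139), and with low RFI libraries 2 and 4 left out as well (0.172, median 0.09). The lineage factor list median was 0.033 without low RFI library 1, -0.27 without 3, -0.24 without high RFI library 4, -0.083 with low RFI library 1 and high RFI library 4 left out and 0.092 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Adjusted over the list alone, 0 members of either list passed.

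Among lists of general cell functions in the pituitary, nuclear-encoded oxidative phosphorylation genes were higher in low RFI, 56 of 65 (median log2 difference 0.08, camera with Benjamini-Hochberg adjusted p = 0.00107; adjusted p = 0.803 with an estimated correlation), with UQCRB at a log2 fold of 0.39. The call was lost without low RFI library 1 (adjusted p = 0.893) or 2 (0.594) or high RFI library 5 (0.0601), and without low RFI library 1 and high RFI library 4 together (0.900). The oxidative phosphorylation median was 0.0042 without low RFI library 1, 0.014 without 2, 0.18 without 3, 0.19 without 4, 0.16 without high RFI library 2, 0.041 without 5, 0.022 with low RFI library 1 and high RFI library 4 left out and -0.056 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. UQCRB was 0.20 without low RFI library 1, 0.23 with high RFI library 4 left out as well, 0.037 with low RFI libraries 2 and 4 also left out, and 0.16 with limma-voom. Cytosolic ribosomal protein genes, a family with many near-identical copies, were lower, 62 of 63 (median -0.10, camera adjusted p = 0.000852; adjusted p = 0.803 with an estimated correlation). Without low RFI library 1 their median turned to 0.05 (adjusted p = 0.0939), and the call was also lost without high RFI library 2 (0.631) and without low RFI library 1 and high RFI library 4 together (0.193). The ribosomal list median was 0.055 without low RFI library 1, -0.16 without 5, -0.063 without high RFI library 1, -0.00055 without 2, -0.17 without 4, -0.016 with low RFI library 1 and high RFI library 4 left out and 0.021 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Chaperone genes were higher, 21 of 27 (median 0.10, camera adjusted p = 0.00801; adjusted p = 0.644 with an estimated correlation), with CHORDC1 at a log2 fold of 0.40. That call was lost without low RFI library 1 (adjusted p = 0.0584) or 2 (0.404) or high RFI library 5 (0.0601). The chaperone list median was 0.066 without low RFI library 1, 0.054 without 2, 0.18 without 3, 0.15 without high RFI library 4 and 0.011 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. Fatty acid and cholesterol synthesis genes were higher, 26 of 34 (median 0.09, camera adjusted p = 0.0241; adjusted p = 0.803 with an estimated correlation), and the call was lost without low RFI library 1 (adjusted p = 0.974) or 2 (0.489) or high RFI library 2 (0.165), 3 (0.243) or 5 (0.127), and without low RFI library 1 and high RFI library 4 together (0.414). The lipid synthesis median was 0.0029 without low RFI library 1, 0.18 without 4, 0.15 without 5, 0.18 without high RFI library 1, 0.055 without 3, 0.062 without 5, 0.038 with low RFI library 1 and high RFI library 4 left out and -0.026 with low RFI libraries 1, 2 and 4 and high RFI library 4 left out. With low RFI libraries 1, 2 and 4 and high RFI library 4 left out, all 4 calls were lost, at adjusted p = 0.406, 0.457, 0.593 and 0.975 in the order given. No member (0) of these 4 lists passed when adjusted over the list alone. The 24 lists not called had adjusted p values from 0.0558 to 0.982, and the median, mean and test differed in sign for the erythrocyte, neighbouring forebrain and mitochondrially encoded lists among them.

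Whether the RFI difference itself differs between the tissues was tested over all 20 libraries. No gene passed (0 of 16747, edgeR quasi-likelihood, smallest Benjamini-Hochberg adjusted p = 1.00), with 392 genes at an unadjusted p under 0.05 where 837.4 would be reached by chance. For CHGB, with a log2 fold of 0.55 in the hypothalamus and -0.20 in the pituitary, the difference of folds was -0.75. For SLC6A13, at 0.70 in the hypothalamus and -1.54 in the pituitary, it was -2.25, and for PDE6B, at 0.51 and -1.21, it was -1.73. Each had an adjusted p of 1.00 (edgeR, Benjamini-Hochberg). DESeq2 called 2 genes (583 at unadjusted p under 0.05) and limma-voom 0 (529). The 2, named after their values were seen, were BARHL1 (DESeq2 adjusted p = 1.21e-18), with 56.5 CPM in pituitary high RFI library 4 and at most 0.252 in the other 9 of that tissue, and DDC (adjusted p = 0.00811, difference of folds -4.07). DDC stood at 69.05 CPM in the same pituitary library, without which the high RFI mean fell from 23.5 to 12.11. In the hypothalamus DDC ran from 10.1 to 124 CPM among low RFI libraries.

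The RFI differences of the tissues were then set against each other over the 14512 genes tested in both. Pearson's r was 0.10, across genes, which are not independent replicates. An exact permutation of the RFI labels of the pituitary libraries over all 252 assignments gave a two-sided p of 0.135. Spearman's rho was 0.17 with an exact permutation p of 0.00794, the smallest the 252 assignments can give. Over the 9745 genes with a mean log2 CPM of at least 3 in both tissues, Pearson's r was 0.17 (exact permutation p = 0.0476). Over all genes it also moved over the threshold when single libraries were left out, to 0.14 without hypothalamus low RFI library 3 (exact permutation p = 0.0317), to 0.13 without hypothalamus high RFI library 3 (p = 0.00794) and to 0.12 without pituitary low RFI library 1 (p = 0.0317), and was 0.02 without hypothalamus high RFI library 5 (p = 0.817). With pituitary low RFI library 1 and high RFI library 4 both left out it was 0.15 (exact permutation p = 0.0286, the smallest those 70 assignments can give), and with pituitary low RFI libraries 2 and 4 left out as well it was 0.09 (exact permutation p = 0.400). This was 1 relation, so no adjustment for other relations applies.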

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

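The genes that first pointed to single libraries were chosen after their values were seen, and the held-out markers tested against them were written before those markers were looked at. Of 268 group values tested for 1 sample far from the other 4, 20 were marked, where chance marks about 1 in 20 (13.4). The gap over range was computed on log2 CPM for genes and lists, and on the values themselves for total counts. For single genes CPM are printed beside it, so the ratio differs from one taken on the printed CPM.

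In hypothalamus pools of low RFI, replicate 1 was lowest for MRAP2 (6.28 CPM against 10.9 to 13.4 in the others, gap over range 0.725) and for CARTPT (2.07 against 9.42 to 13, 0.823), and replicate 3 had the lowest total count (11400000 against 12400000 to 12500000, 0.847). In hypothalamus pools of high RFI, replicate 5 was highest for NPVF (51.5 CPM against 6.15 to 11.4, 0.712) and TRH (14.4 against 2.28 to 3, 0.855), and replicate 4 for SST (136 against 72.1 to 75.5, 0.929).

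In pituitary pools of low RFI, replicate 2 was lowest for FSHB (86.8 CPM against 585 to 1110, 0.750) and CHGB (463 against 612 to 677, 0.737), replicate 1 lowest for AVPR1B (77.9 against 193 to 241, 0.805) and highest for AVP (100 against 0.261 to 1.73, 0.730), replicate 5 lowest for ADAMTS2 (23.8 against 28.2 to 29.5, 0.790), and replicate 4 highest for FOLR1 (93.7 against 0.729 to 1.84, 0.828). In pituitary pools of high RFI, replicate 4 was highest for NKX2-1 (27.6 CPM against 6.67 to 9.98, 0.718) and PTGS2 (128 against 32.1 to 37.5, 0.887) and lowest for GHRHR (131 against 198 to 229, 0.740), and replicate 1 was lowest for WDR31 (1.98 against 3.21 to 3.86, 0.719). Replicate 2 was highest for C1QA (28.7 CPM against 14.1 to 16.5, 0.777) and AVP (8.27 against 1.42 to 1.77, 0.879), and for the mean log2 CPM of the fibroblast and meninges list (7.32 against 5.93 to 6.32, 0.717) and of the inflammation list (4.28 against 3.87 to 3.97, 0.764).

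RNA of a neighbouring tissue is a candidate explanation for the libraries that stood apart, and no biological explanation was tested. Hypothalamus low RFI library 2 was the highest of 10 for 5 of 7 detected held-out pineal markers (one-sided exact binomial p = 0.000177, Benjamini-Hochberg over 5 tests 0.000294), pituitary high RFI library 4 for 5 of 7 cerebellum markers (p = 0.000177, adjusted 0.000294), pituitary low RFI library 2 for 6 of 7 sensory ganglion markers (p = 6.4e-06, adjusted 3.2e-05), and pituitary low RFI library 4 for 5 of 8 respiratory epithelium markers (p = 0.000432, adjusted 0.00054). For thalamus or other diencephalon RNA in pituitary low RFI library 1 the count was 3 of 8 (exact p = 0.0381), fewer than the share asked for beforehand, which leaves it open. The binomial counts marker genes as independent, with a chance of 1 in 10 each. Genes of 1 library vary together, and these libraries were chosen because they stood apart. No share over other genes was taken. These p values therefore do not measure evidence for the named tissue. Abundant genes seen were TTR at 23400 CPM, CBLN1 at 732, SCN11A at 542, SPIK5 at 1050 and GAD1 at 228 CPM in those libraries in the order pineal, cerebellum, ganglion, epithelium and diencephalon. The other libraries also expressed, at a median of at least 1 CPM, 4, 5, 5, 7 and 5 of the held-out genes in that order, and fixed lists hold 1 of the pineal and 4 of the diencephalon genes.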

How the results depend on the processing

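The fits without some pituitary libraries and with the small-chromosome score were chosen after the data were seen. So were the swaps inside blocks for the correlation between tissues. Where counts or calls changed, the cause was not tested. Genes called were 5 in the hypothalamus with DESeq2 (0 with edgeR, 728 at unadjusted p under 0.05), 1 in the pituitary on log2(FPKM + 0.1), and for the tissue difference 2 with DESeq2 and 1 on log2(FPKM + 1) with no filter; all other fits of these 3 comparisons gave 0. Lists called were 0 in each tissue with an estimated correlation and 0 with fry; leaving out 1 library gave 4 to 15 in the hypothalamus and 13 to 24 in the pituitary. The correlation between tissues was 0.17 as Spearman's rho (exact permutation p = 0.00794), 0.17 over genes with mean log2 CPM of at least 3 (exact permutation p = 0.0476), 0.150 without pituitary low RFI library 1 and high RFI library 4 (exact permutation p = 0.0286), and 0.0208 to 0.144 with 1 library left out. Without pituitary low RFI libraries 1, 2 and 4 and high RFI library 4 the median log2 difference turned in 5 lists: lineage factors and receptors 0.0925, oxidative phosphorylation -0.0564, ribosomal proteins 0.0215, lipid synthesis -0.0264 and synapse -0.119. With 1 library left out it ran from -0.173 to 0.0550 for ribosomal proteins, -0.137 to 0.553 for synapse and -0.0653 to 0.339 for choroid plexus and ependyma. The pituitary AVP log2 fold of 2.88 was -1.18 with limma-voom, -1.70 without low RFI library 1 and high RFI library 4, -2.15 without all 4, and -1.54 to 3.81 with 1 library left out. COL1A2 in the hypothalamus (0.55) turned to -0.48 with the score, which also moved CHGB to 0.97, SCG2 to 0.72, PCSK2 to 0.66, IFIT5 to 2.67, SOX10 to -0.58, GLUL to -0.089, TPH2 to 1.64, MRAP2 to 0.91, HTR1B to 0.71 and IGFBP2 to 0.42. Limma-voom moved GCH1 to 1.40, TPH2 to 1.63, SLC6A4 to 1.61 and COL1A2 to 0.26 in the hypothalamus, and in the pituitary SLCO1C1 to -1.12, NKX2-1 to -0.83, PTGS2 to -0.44, CSF1R to -0.42, ALDH1A2 to -0.23, C1QA to -0.17, CHORDC1 to 0.25 and SYT2 to 0.53. Leaving out the 4 pituitary libraries moved DGKH to 0.67, COMTD1 to 0.39, WDR31 to 0.37, VIP to -0.55, HDC to -0.30, SLCO1C1 to -0.61, PTGS2 to -0.22, NFKBIA to 0.29, SYT2 to 0.44, CSF1R to -0.40, C1QA to -0.09 and FOLR1 (5.05) to 1.53. Leaving out 2 of them, low RFI library 1 and high RFI library 4, moved HDC to -0.81, NKX2-1 to -0.66, PTGS2 to -0.30, C1QA to -0.17 and SYT2 to 1.13. FOLR1 was 1.19 without low RFI library 4. Of 71 named gene folds, 42 moved over 1.5 times in an alternative and 23 with 1 library left out. Named gene folds kept direction and side of the threshold in 1165 fits, called lists in 262 and lost the call in 116. In simulation with genes drawn independently, 32.8% of 1.5-fold changes were recovered in the hypothalamus and 2.99% in the pituitary, where the median standard error of a log2 fold was 0.16 and 0.23.

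The labels do not say that replicate numbers pair the libraries. Correlations of same-numbered deviations ran from -0.109 to 0.145 between hypothalamus groups (0 of 5 best with their own number) and from -0.0804 to 0.361 between pituitary groups (1 of 5). Across tissues they ran from -0.306 to 0.254 in low RFI (1 of 5) and from -0.0523 to 0.0224 in high RFI (0 of 5). Low correlations cannot show that same-numbered libraries of the tissues hold different birds, so pairing stays open. With the replicate number as a block, edgeR called 0 genes in the hypothalamus (519 at unadjusted p under 0.05), the pituitary (241) and for the tissue difference (253), camera 8 and 20 lists, the AVP fold was -0.43, that of SYT2 1.12 and that of FOLR1 2.40, and the correlation between tissues was 0.10 (exact permutation p = 0.0625, the smallest its 32 swaps allow).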

Other observations

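The 2 tests of cholinergic genes alone and the small-chromosome score were chosen after the result was seen, as were the genes SLC18A3 and SLC10A4.

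Energy-sensing genes of the hypothalamus, which couple nutrient state to growth, were not called (camera in limma, Benjamini-Hochberg adjusted p = 0.907). AKT2, an insulin-pathway kinase gene, had a log2 fold of -0.28, FOXO1 -0.34 and the translation factor gene EIF4E 0.21. Astrocyte and tanycyte genes were not called either (adjusted p = 0.169), with GFAP at -0.47 and glutamine synthetase (GLUL) at -0.33.

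For the gene lists, chance cannot be excluded: 71 of 100 splits of the hypothalamus libraries, the real one included, gave at least the real 7 lists (highest other 20), and 30 of 100 gave at least the real 18 in the pituitary (highest other 24). For single genes the real count was 0, which every split reaches by construction (100 of 100 in the hypothalamus, 100 of 100 in the pituitary and 60 of 60 for the tissue difference), so that count says nothing about chance; its highest other values were 1513, 3 and 3 genes. At an unadjusted p under 0.05, 40 of 100 splits reached the real 728 genes in the hypothalamus (highest other 4324), 88 of 100 the real 296 in the pituitary (3291) and 57 of 60 the real 392 for the tissue difference (3088), so chance cannot be excluded there. The hypothalamus split with 1513 genes set low RFI libraries 1 and 5 and high RFI libraries 2, 3 and 5 against the others; it is the highest of those drawn, named after its value was seen, and points to some structure of the samples, which was not tested.

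Genes lower in low RFI hypothalamus lay on small chromosomes and unplaced scaffolds more than others did: at an unadjusted p under 0.05, 100 of 834 tested genes on chromosomes 16, 25 and 30 to 33 were lower and 3 higher. The median on unplaced scaffolds was -0.315 (SE 0.0429), which restates the pattern and supports no trend by chromosome class, a stand-in for GC content, as its cause. A score of the small-chromosome genes per library was -0.0892 ± 0.0563 in low and 0.0892 ± 0.0837 in high RFI (SD, n = 5 each); it averages the same gene classes, so it restates the pattern too. With the score as a covariate edgeR called 0 genes (862 at unadjusted p under 0.05), but score and group do not overlap, GC content itself was not analysed here, and RFI stays open.

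Cholinergic and serotonergic genes were higher in low RFI hypothalamus, but peaked in different libraries. CHAT lay above every high RFI library in all 5 low RFI libraries. CHAT and SLC5A7 were highest in low RFI library 5 (12.2 and 25.1 CPM), where TPH2 was 8.17 and FEV 0.707. TPH2 and FEV were highest in low RFI libraries 3 and 4 (TPH2 146 and 119, FEV 12.9 and 10.9 CPM). More midbrain or pontine tissue in libraries 3 and 4 may account for the serotonergic genes there. GCH1 was instead highest in low RFI library 2 (44.3 CPM), which also held the TTR and ASMT reads. A source shared by the cholinergic and the serotonergic genes is not shown. Across the 10 libraries, the mean of 9 detected held-out midbrain, pontine and raphe genes (in low RFI library 4, PRPH at 68.7, EN1 at 20.2 and FEV at 10.9 CPM) correlated with that of 8 genes (CHAT, SLC5A7, SLC18A3, SLC10A4, TPH2, SLC6A4, DDC and GCH1) at r = 0.858 (permutation p = 0.00204, adjusted 0.00816) and rho = 0.842 (permutation p = 0.00383, adjusted 0.0153), with r = 0.574 without the 2 farthest libraries. FEV among the 9, and TPH2 and SLC6A4 among the 8, were all highest in low RFI libraries 3 and 4. Any rise of serotonergic genes there would raise this r. It therefore cannot tell added midbrain or pontine tissue from such a rise. Basal forebrain tissue would not raise the serotonergic genes, so r = 0.045 over its 5 genes (permutation p = 0.905, adjusted 0.905; rho 0.0182, permutation p = 0.974, adjusted 0.974; r = 0.245 without 2) argues against it only as a source of all 8, and against CHAT, SLC5A7 and SLC18A3 r was -0.331 (permutation p = 0.351, adjusted 0.468; rho -0.212, permutation p = 0.561, adjusted 0.748; r = -0.109 without 2). For these 3 genes and the midbrain, pontine and raphe genes r was 0.491 (permutation p = 0.151, adjusted 0.302; rho 0.673, permutation p = 0.0394, adjusted 0.0787; r = 0.259 without 2), and a source in midbrain or pontine tissue and one in RFI cannot be told apart for them. Adjusted values are Benjamini-Hochberg over 4 relations with 100000 permutations each, and 4 of the 9 midbrain, pontine and raphe genes and 2 of the 5 basal forebrain genes reach a median of 1 CPM in the hypothalamus libraries.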
